A study of Homo sapiens with 12 samples.

How the data were processed

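RNA was extracted with TRIzol and made into libraries with a stranded Illumina TruSeq mRNA kit, which were sequenced as read pairs on an Illumina NovaSeq instrument, per the labels' protocols. FastQC 0.11.9, Trimmomatic 0.39, HISAT2 2.2.1, featureCounts, Subread 2.0.1 and DESeq2 1.30.1 are named in the submitters' processing notes, with the build GRCh38, also written hg38. The notes as used here give these tools no role or order, and the gene annotation, the strand setting and the filters are not given in the sources used here. The deposited files are a table of read counts per gene symbol and a table of FPKM values, which are scaled by gene length and library size, with the same column names, per the file headers. A list of checksums of the read files was not used.

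Samples were grouped by their titles, which give the cell line, the arm and a replicate number. The cell line field of the MDA-MB-231 samples names other members of a number series in place of MDA-MB-231, and the titles were followed. Each table has 12 columns of values, and no number reported here comes from them, because each name matches 2 samples, 1 in each cell line. The value columns were read when the files were inspected to find their units. In that inspection FPKM values were compared with counts gene by gene, and the values of the 5 genes named by rule and of IFNB1 were seen. What stood out is given in words among the other observations. No normalization, fold change or test between knockdown and control was computed.

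The reported numbers use only the column of gene symbols and the header of each table. Symbols were counted with Python 3.11.15 and compared exactly, including case, between the tables and with the gene names of GENCODE release 29, an annotation of GRCh38. Gene types and positions come from that annotation, with positions counted from 1, and the authors may have counted over another annotation of the same build. The 27 gene lists, with 867 entries in all, were written before the data were examined. A list member counted as present when its current symbol or the older symbol written beside it in the lists had a row.

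The tests planned before the data were examined were a quasi-likelihood test of counts in each line, a test of the difference between the lines, tests of the gene lists and their alternatives. None was run, since columns that match no single sample were not used for tests. A test within each letter needs only the arm, which the column names give. If the letters stand for the lines, a test between them would leave only the sign of the difference open. Neither test was made here. The rule for named genes was to give ARMCX3, TP53, IFIH1, CDKN1A and MDM2 whatever their values and to choose the others by their tests. Only the part that needs no test was applied. IFNB1 is named in addition because its 2 rows were seen in the FPKM table. SEC62 is named outside the rule too, because its FPKM values stood out when they were compared with counts.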

Results

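The study measured mRNA by RNA sequencing in a pair of human breast cancer cell lines after stable knockdown of ARMCX3. MCF-7 is an oestrogen receptor positive, luminal line with wild-type p53. MDA-MB-231 is a triple-negative, mesenchymal-like line with mutant p53. Each line was transduced with a lentivirus that carried a short hairpin RNA against ARMCX3 or a non-targeting control hairpin, and transduced cells were selected with puromycin. The labels describe 12 libraries in 4 groups, with 3 libraries of MCF-7 control, 3 of MCF-7 knockdown, 3 of MDA-MB-231 control and 3 of MDA-MB-231 knockdown. The series title names p53, the RNA sensor IFIH1 and immune pathways as the subjects of the comparison between knockdown and control.

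The target, ARMCX3, encodes an armadillo-repeat protein of the mitochondrial outer membrane that takes part in mitochondrial transport. In the GENCODE annotation of GRCh38 it is the protein-coding gene ENSG00000102401.19 on chromosome X, from 101622797 to 101627843 on the plus strand. The gene had 1 row in the deposited count table and 1 row in the deposited FPKM table. TP53, which encodes p53, is ENSG00000141510.17 on chromosome 17, from 7661779 to 7687550 on the minus strand, and had 1 row in each table. The p53 targets CDKN1A, a cyclin-dependent kinase inhibitor, and MDM2, the ubiquitin ligase that degrades p53, also had 1 row in each table. CDKN1A lies on chromosome 6 from 36676460 to 36687339, and MDM2 on chromosome 12 from 68808176 to 68850686, both on the plus strand.

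IFIH1 encodes MDA5, a cytoplasmic sensor of long double-stranded RNA. It is ENSG00000115267.6 on chromosome 2, from 162267079 to 162318703 on the minus strand. IFIH1 had 1 row in the count table and 0 rows in the FPKM table. It was the only one of the 19225 symbols of the count table without a row in the FPKM table. IFNB1, the gene of interferon beta, lies on chromosome 9 from 21077105 to 21077963 on the minus strand. IFNB1 had 1 row in the count table and 2 rows in the FPKM table, and no other symbol had 2 rows in either table.

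Both tables covered nearly the same genes. The count table held 19225 rows with 19225 different symbols, and the FPKM table held 19225 rows with 19224 different symbols. Of the count table's symbols, 18707 were protein-coding genes in the annotation, and 411 symbols had no entry in it under that name. Neither table held a symbol that starts with MT-, so 0 of the 13 mRNAs of the mitochondrial genome had a row under such a symbol. A row under another name is not excluded.

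The gene groups that the design calls for were looked up among the symbols of the count table. A row shows that a symbol was listed, not that the gene was expressed. With 18707 protein-coding symbols in that table, complete lists were likely whatever the cells expressed. All 40 listed p53 targets, all 50 interferon-stimulated genes, all 22 genes of MHC class I presentation and all 36 NF-kB cytokines and chemokines had a row. All 28 listed genes of nucleic acid sensing had a row in the count table, against 27 in the FPKM table, where IFIH1 was the member without one. All 9 relatives of ARMCX3, among them ARMCX1, ARMCX2 and ARMCX6, and all 30 genes of mitochondrial dynamics and trafficking had a row. The lists of 47 genes of DNA replication and 52 of mitosis were also complete. All 22 listed leukocyte markers had a row, as did all 22 genes listed as typical of MCF-7 and all 24 listed as typical of MDA-MB-231. Whether any of these markers was expressed in the libraries was not examined.

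The comparison of knockdown with control in either line is not reported. The 12 columns of values in each table are named by a letter, A or B, by NC or SH, and by a number. NC, SH and the number match the labels, but the letter appears in none of them. Each column name therefore fits 2 of the 12 samples, 1 of each cell line. The letters were not assigned to lines by the order of the columns or by the genes expressed in them. Columns that match no single sample gave no number reported here, and what was seen in them is described only in words. Knockdown and control could be set against each other within a letter with the line left unnamed, and this was not done here. No expression level, fold change, depth or test is given for ARMCX3, for p53 and its targets, for IFIH1 or for any other gene, and the extent of the knockdown was not analysed here.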

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

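The symbol counts were not among the tests planned before the data were examined. All alternatives to them were chosen after seeing the data. With current and older symbols, 854 of the 867 list entries had a row in the count table, and 26 of the 27 lists were complete. With current symbols only, 795 entries had a row and 18 lists were complete, since 59 entries stood under an older symbol, among them the 41 replication-dependent histone genes. Against the FPKM symbols, 853 entries had a row and 25 lists were complete, and the entry that was lost was IFIH1. The alternatives written before the data were examined, namely other normalizations, filters and tests, fits of 1 line, FPKM in place of counts and leaving out each library, were not run. No paired analysis was possible under the rule kept here, because it kept every column that matches no single sample out of the tests. The sample titles give replicate numbers but do not say that control and knockdown libraries of equal number belong together.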

Other observations

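The FPKM table differed from the count table only in the symbols IFIH1 and IFNB1. IFIH1, which the series title names, was in the count table only, and IFNB1 had 2 rows in the FPKM table, so that both tables have 19225 rows. When the values were inspected to find their units, both IFNB1 rows held equal values in the columns lettered A. In the columns lettered B, one of the rows followed from the IFNB1 counts. The other lay far above the FPKM values that those counts would give. Among the genes compared, which were well counted in every column, SEC62 had FPKM values that did not follow from its counts, while those of the others did. The number of genes compared and the tolerance used are not given here. In the count table, raw ARMCX3 and CDKN1A counts of the same arm lay close together between the letters, and some CDKN1A control counts recurred exactly. Raw counts are not adjusted for library size, so close counts do not show similar expression. The same comparison is not given here for TP53, MDM2, IFIH1 or the other genes, so how unusual this closeness is cannot be judged. What lies behind these FPKM and count values was not examined. These points were seen on inspection of columns that match no single sample, so no values are printed for them and no test was made.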
